A study of Rattus norvegicus with 15 samples.

How the data were processed

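MicroRNAs (miRNAs) were measured on 15 rat miRNA arrays, each hybridised with total RNA from sciatic nerve of adult male rats. The labels give 5 groups of 3 arrays: uninjured nerve (day 0) and injured nerve on days 1, 4, 7 and 14. The descriptions of the injury differ. The series text gives a resection and proximal nerve tissue of 0.5 cm, whereas the treatment protocol gives a crush and damaged sections of about 0.5 mm, and the samples are named both proximal stumps and injury site. The word injury is used here for both. Per the labels, RNA was prepared with a mirVana kit, and 0.1 µg was labelled with cyanine 3. Nothing in the labels pairs animals across groups by replicate number, so arrays were treated as independent, and the p-values measure the spread between these samples.

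The deposited array files hold spot intensity values made with Agilent Feature Extraction 10.7.3.1, per the file headers. These intensity values are background-subtracted per spot and carry no scaling between arrays. Each array has 7000 spots for 350 rat miRNAs, read by 938 probes, with 2 probes for 222 miRNAs and 4 for 116. The deposited value table is on a log2 scale, found from its values: its columns had r of 0.9963 or more with the log2 total signal of their own array, and all had the same median, 4.1158, except day 14 replicate 3 with 0.8341. That table looked quantile-normalised, lacked miR-17-5p and was used only as an alternative source. The annotation of rat genes was used only to match miRNA names and find neighbouring genes. Names are those printed on the array, an older naming in which an asterisk marks the less abundant arm of a hairpin. Short probes can take up signal from close family members, such as those of let-7, so values of relatives are not independent.

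Spots marked as outliers by the scanner software and control spots were left out. The background-subtracted intensity was averaged over the spots of a probe and then over the probes of a miRNA. Each array was divided by its 75th percentile, taken over the 164 miRNAs detected on all 15 arrays. Values below a floor of 0.00362 (log2 of -8.11) were set to it, and values were then log2-transformed. A miRNA was called detected where the software's detection call was positive, and 231 miRNAs detected on all 3 arrays of at least 1 group were tested. Data were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Depth on an array is signal over background, and the 3 arrays per group limit the precision.

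Differences were tested with limma 3.58.1 in R 4.3.3, in one model of the 5 group means with 10 residual and 3.28 prior degrees of freedom. The tests are two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 231 miRNAs within each comparison, with a threshold of 0.05. Errors beside a log2 change are standard errors from this model, with n = 3 arrays per group, unless SD is written. The comparisons were each injured group against day 0, each time against the time before it, and an F test over all 5 groups. A miRNA not detected on any array of one group was given a lower bound: "at least N-fold" compares the detected group with the lowest value of any detected miRNA on each array of the other group, or with the miRNA's own value there where that was larger. No fold was given where neither group had a detection.

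The following choices were made before the data were examined. A rule set which miRNAs are named: for each comparison with day 0, the 10 largest rises and the 10 largest falls that passed the test with all 3 arrays beyond all 3 day 0 arrays, 17 miRNAs whatever their result, and up to 4 members per list with the smallest adjusted p. For consecutive times the rule took 5 rises and 5 falls, and for the F test 10 miRNAs. A few of the named list members are summarised as counts. The 22 lists covered cell types (muscle, neuron, myelinating glia, leukocyte, erythrocyte, endothelium, smooth muscle and fibroblast, epithelium, liver and pancreas), inducible miRNAs (inflammation, hypoxia) and families or clusters (let-7, miR-10/196, miR-15/16 with miR-322 and miR-503, miR-17-92, miR-23/24/27, miR-29, miR-30, miR-34, miR-181, miR-221 with miR-222, Dlk1-Dio3). The 17 lists with at least 3 tested members were tested with limma's camera at its preset correlation of 0.01, giving 68 tests adjusted together; camera with an estimated correlation and fry were run beside it.

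The limma step was tested on simulated log2 values with 60 changed miRNAs of 231 in each of 20 sets, as many raised as lowered. Noise was independent between miRNAs, and scaling, floor, detection filter and slide effects were not simulated, so errors from these are not covered. The limma step recovered 79.2% of 1.5-fold, 93% of 2-fold and 98.2% of 4-fold changes, and 3.05% of its calls were false. With no change it made 0.05 calls per comparison.

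Arrays lay on 5 slides scanned on 4 days. Day 0 and day 1 were each scanned on a date of their own. Day 4, day 7 and day 14 replicates 1 and 2 shared a scan date, and day 14 replicate 3 had another. Day 0, day 1 and day 4 each filled a slide of their own, day 7 shared a slide with day 14 replicates 1 and 2, and day 14 replicate 3 was on another slide. Every comparison with day 0, and those of day 4 with day 1 and day 7 with day 4, therefore lies between slides, and slide and group cannot be told apart in them. Alternatives covered the scaling (75th percentile over all miRNAs, quantile, none), the summary over probes, the floor, the detection filter, the deposited table, the variance model, blocks for replicate number or slide, a 2-fold minimum and leaving out each array in turn. The planned normexp correction of mean spot signals was not run, because the array files used here give median signals. Normexp with an offset of 50 on the median signals, scaling by bright control features, leaving out both day 0 replicate 1 and day 14 replicate 3, and leaving out the muscle and erythrocyte lists were added after seeing the data. A call is described as held under 5 scalings when the direction and the call were the same with the main scaling, the 75th percentile over all miRNAs, quantile normalisation, no scaling and the deposited table.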

Results

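Levels of 350 rat miRNAs were measured in sciatic nerve before injury (day 0) and on days 1, 4, 7 and 14 after it, with 3 arrays per group. Of the 350 miRNAs, 164 were detected on all 15 arrays and 97 on none. Between 200 and 239 miRNAs were detected per array, except on day 14 replicate 3 with 172. On that array the negative controls averaged an intensity of -8.54 and the software placed the additive error, 14.8, outside its range. Outlier spots made up 5.67% there and 2.66% to 4.17% elsewhere, and no spot was saturated. The bright corner control feature was at 82.7 to 107 on the day 1 arrays and at 834 to 2549 on the others. Whether this difference of the day 1 slide bears on the day 1 calls was not tested. The brightest miRNA was miR-125b-5p on every day 0 and day 1 array, with 7.24% to 8.37% of the total signal, and miR-21 on every array from day 4 on, with 9.19% to 16.1%. Probes can differ in their binding, so signal does not rank abundance across miRNAs. Across miRNAs, which are not independent replicates, the correlation between arrays of a group was lowest on day 0, at 0.973, and highest on day 4, at 0.998.

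The day 1 comparison asks what the nerve's miRNAs did within a day of injury. miR-31 was not detected in uninjured nerve and was at least 6.61-fold higher on day 1. miR-223, abundant in neutrophils and other myeloid cells, rose by 1.79 ± 0.16 on the log2 scale (3.46-fold), and the blood-cell miRNAs miR-142-3p and miR-142-5p rose by 0.82 ± 0.13 and 1.00 ± 0.14. miR-21, which is induced by inflammatory and growth signals, rose 2.85-fold (log2 1.51 ± 0.12), and miR-132, induced by CREB in active neurons, was at least 2.74-fold higher. miR-338, encoded in an intron of the Aatk gene and abundant in myelinating glia, fell by 0.83 ± 0.16. All 8 tested members of the let-7 family, which promotes differentiation, fell under the main scaling, and 3 to 8 passed as falls under the other 4.

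Of 231 miRNAs, 140 passed the test on day 1, 39 higher and 101 lower. The groups did not overlap for 124 miRNAs (53.7%; chance gives 10%). The median change over all tested miRNAs was -0.26, so that the split between rises and falls moved with the scaling: it was 57 to 85 with the 75th percentile over all miRNAs, 57 to 87 with quantile normalisation, 32 to 127 without scaling and 48 to 61 in the deposited table. The calls held under 5 scalings for 24 rises and 57 falls. Without day 14 replicate 3, which changes the miRNAs used for the scaling, 58 rose and 68 fell, with a median change of -0.04.

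Other large rises on day 1 were those of miR-188 (2.08 ± 0.44, adjusted p = 0.00123), miR-327 (1.75 ± 0.49, adjusted p = 0.00734) and miR-18a (1.68 ± 0.16, adjusted p = 2.04e-06), each detected on 1 of 3 day 0 arrays. Not detected on day 0 were miR-130b, miR-760-3p and miR-21*, which were at least 3.34-fold, 2.63-fold and 1.87-fold higher, and miR-34c, at least 1.7-fold higher and detected on 1 day 1 array. The rise of miR-21* was 0.32 with the software's total signal and did not pass there. miR-221 and miR-222, which repress the cell cycle inhibitor p27, rose by 0.77 ± 0.10 and 1.25 ± 0.19. The largest falls were those of miR-191 (-1.53 ± 0.26, adjusted p = 0.000277) and miR-32 (-1.34 ± 0.21, adjusted p = 0.000146). miR-211, encoded in the melanocyte gene Trpm1, was at least 2.15-fold lower and was not detected on any day 1 array. Further falls were those of let-7d* (-1.27 ± 0.31), miR-196c (-1.12 ± 0.09), miR-542-3p (-1.09 ± 0.14) and miR-450a (-1.003 ± 0.119), while miR-377 and let-7b* were at least 2.08-fold and 1.73-fold lower. miR-92b passed the test but was not detected on any array of either group, so no fold is given. miR-1, miR-138, miR-206, miR-210, miR-29a, miR-34a and miR-140 did not pass, with log2 changes of -0.0005, -0.01, 0.73, 0.18, 0.09, -0.18 and -0.20. Several of these rested on 1 array: without day 0 replicate 1, miR-1 changed by 1.42 (adjusted p = 0.0661), miR-206 by 2.14 (adjusted p = 0.0161) and miR-140 by -0.29 (adjusted p = 0.0127), and without both that array and day 14 replicate 3 miR-1 changed by 1.66 (adjusted p = 0.0427). Without day 14 replicate 3, miR-29a and miR-210 changed by 0.30 and 0.39 and passed. miR-9, a neural miRNA, fell by 0.51 ± 0.15, and miR-182 rose by 1.00 ± 0.20.

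By list on day 1, let-7 had 0 rises and 8 falls (mean log2 change -0.58, camera adjusted p = 0.028), and the miR-10 and miR-196 genes, which lie within the Hox clusters, had 0 and 5 (mean -0.77, adjusted p = 0.028). Neither these nor any other of the 12 list calls made over the 4 times held with an estimated correlation, where every adjusted p = 0.728 or more. For let-7 this depended on the scaling: falls numbered 4 with quantile normalisation (mean -0.22) and 3 in the deposited table (mean -0.20), and the list was not called there or without scaling. The miR-10 and miR-196 genes had 5 falls under each scaling, but the list was not called without scaling. The miR-17-92 cluster and its paralogs, driven by MYC in dividing cells, had 5 rises and 1 fall of 11 (mean 0.28, adjusted p = 0.028), among them miR-17-5p (0.42 ± 0.11), miR-20a (0.39 ± 0.11) and the fall of miR-363 (-0.41 ± 0.14); without scaling it had 1 rise and 2 falls (mean 0.13) and was not called, and with the other 3 scalings it had 8 or 9 rises. The leukocyte list had 3 rises and 0 falls of 5 (mean 0.68, adjusted p = 0.036) and was not called with quantile normalisation or without scaling. The neuron list had 4 rises and 2 falls of 8 (mean 0.41, adjusted p = 0.0448), with rises of miR-124 (0.92 ± 0.16), miR-137 (0.80 ± 0.16) and miR-7a (0.64 ± 0.10), and was not called under any of the other 4 scalings. The other lists did not pass as sets, and their counts were as follows. The inflammation-inducible list had 2 rises and 1 fall of 3, the fall being that of miR-146a (-0.70 ± 0.10) beside a rise of miR-146b (0.55 ± 0.13), both targets of NF-kB signalling. Myelinating glia had 0 rises and 4 falls of 5, smooth muscle and fibroblast 1 and 3 of 5, epithelium 2 and 0 of 5, and miR-15/16 with miR-322 and miR-503 had 0 and 3 of 6. The families had 1 rise of 3 for miR-29 and 1 of 3 for miR-34, and 0 rises each with 2 falls of 5 for miR-30, 1 of 4 for miR-181 and 3 of 5 for miR-23/24/27. Dlk1-Dio3, an imprinted region whose miRNAs are expressed from the maternal copy, had 2 rises and 18 falls of 30, among them miR-299 (-0.93 ± 0.10). Lists too small for a set test had 2 rises of 2 for miR-221 with miR-222, 2 falls of 2 for endothelium (miR-126* -0.77 ± 0.10), 1 fall of 2 for liver and pancreas, 1 rise of 2 for erythrocyte and 0 of 1 for hypoxia.

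Markers of muscle and red blood cells varied between arrays of the same group. The muscle miRNA miR-1 was at a log2 level of 3.12 on day 0 replicate 1 and at -1.52 and -0.76 on the other day 0 arrays. The muscle list had 0 rises and 1 fall of 5 on day 1, miR-499 (-0.58 ± 0.18). The erythroid miR-451 rose 2.83-fold (adjusted p = 0.0365) with overlapping groups; without day 0 replicate 3 the rise was 0.73, with adjusted p = 0.178. Its neighbour miR-144 changed by 0.96 ± 0.58 and did not pass.

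**Figure D1:**
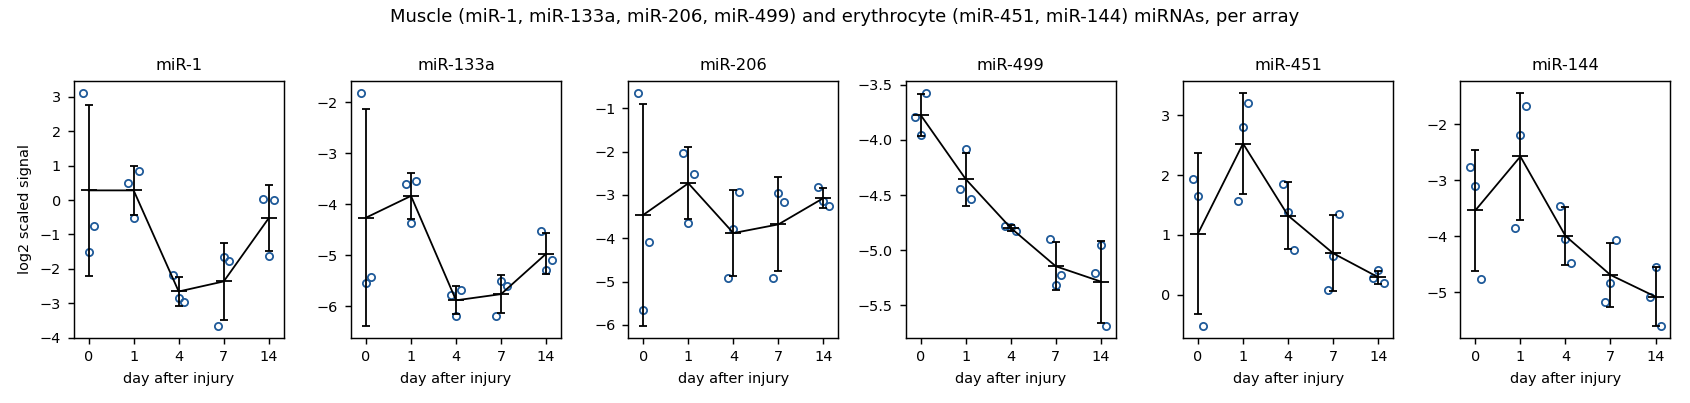
Log2 scaled signal (y axis) of muscle and erythrocyte miRNAs by day after injury (x axis); points are arrays, the line joins group means and bars are SD (n = 3). The 3 day 0 arrays spread from -1.52 to 3.12 for miR-1.

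On day 4, miR-31 was at least 47.9-fold higher than in uninjured nerve, at a log2 level of -1.96 ± 0.19 (SD, n = 3) against a day 0 value at the floor. miR-21 was 8.16-fold higher (log2 3.03 ± 0.12), moving from a level of 1.98 ± 0.14 (SD, n = 3) to 5.01 ± 0.18. miR-221 rose 4.08-fold and miR-18a, a member of the proliferation-linked miR-17-92 cluster, 6.10-fold. The glial miR-338 fell by 1.27 ± 0.16, miR-138, abundant in nervous tissue, fell by 0.97 ± 0.17, and miR-33, which lies within a gene of sterol regulation and represses cholesterol export, fell by 1.89 ± 0.19. All of these held under 5 scalings.

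On day 4, 152 of 231 miRNAs passed the test, 47 higher and 105 lower, and the groups did not overlap for 178 (77.1%; chance gives 10%). The median change was -0.26. The split was 74 to 74 with the 75th percentile over all miRNAs, 68 to 86 with quantile normalisation, 33 to 124 without scaling and 61 to 76 in the deposited table, and 29 rises and 56 falls held under 5 scalings. Without day 14 replicate 3, 63 rose and 86 fell.

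Further rises on day 4 were those of miR-222 (2.19 ± 0.19, adjusted p = 5.54e-07), miR-146b (1.42 ± 0.13), miR-34b (1.39 ± 0.15), miR-142-3p (1.16 ± 0.13), miR-223 (1.14 ± 0.16) and miR-142-5p (1.06 ± 0.14). miR-130b, miR-132, miR-34c, miR-21* and miR-878, not detected on day 0, were at least 7.00-fold, 4.84-fold, 4.11-fold, 3.21-fold and 2.46-fold higher. miR-34b and miR-34c belong to a p53-induced family. Further falls were those of miR-32 (-1.67 ± 0.21), miR-9* (-1.13 ± 0.13), miR-99a (-1.11 ± 0.13), miR-301a (-1.06 ± 0.16), miR-26b (-1.04 ± 0.10), miR-10b (-1.04 ± 0.10) and miR-9 (-1.03 ± 0.15). miR-1 fell by 2.94 ± 0.96 (adjusted p = 0.015), but without day 0 replicate 1 the change was -1.52 and did not pass (adjusted p = 0.0515). miR-29a rose by 0.32 ± 0.11. miR-140 fell by 0.26 ± 0.09, with the opposite sign under the 75th percentile over all miRNAs, quantile normalisation and the deposited table. miR-34a (-0.20), miR-182 (0.30), miR-206 (-0.42), miR-210 (-0.04) and miR-451 (0.30) did not pass.

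Among the lists on day 4, let-7 again had 0 rises and 8 falls (mean -0.78, camera adjusted p = 0.019), led by let-7c (-0.91 ± 0.10) and miR-98 (-0.90 ± 0.10). With quantile normalisation and in the deposited table it had 4 falls each (means -0.26 and -0.24), and it was not called there or without scaling. The miR-17-92 list had 8 rises and 2 falls of 11 (mean 0.63, adjusted p = 0.0063), with rises of miR-19a (1.23 ± 0.15), miR-20a (0.98 ± 0.11) and miR-19b (0.90 ± 0.10). These were the only list calls on day 4, and neither held with an estimated correlation (adjusted p = 0.728). Myelinating glia had 0 rises and 5 falls of 5 (mean -1.05, camera adjusted p = 0.0883), with 3 falls with quantile normalisation and 4 in the deposited table. Fry, which asks only whether the members move one way, gave this list an adjusted p = 0.000186. It was also small for other lists that camera did not call, such as miR-10/196 (fry adjusted p = 9.85e-06) and miR-30 (0.000218), so it is not particular to glia. The miR-10/196 list had 0 and 5 of 5, and miR-30 had 0 and 5 of 5, led by miR-30c (-0.95 ± 0.11). The neuron list had 3 rises and 2 falls of 8, with miR-7a up (1.21 ± 0.10) and miR-218, a motor neuron miRNA, down (-0.75 ± 0.14). The leukocyte list had 3 rises and 1 fall of 5, the fall being that of miR-150 (-0.60 ± 0.11), abundant in mature lymphocytes. The inflammation list had 2 and 1 of 3, with miR-146a lower (-0.68 ± 0.10). miR-15/16 with miR-322 and miR-503 had 2 rises (miR-503 1.12 ± 0.13, miR-15b 0.68 ± 0.10) and 3 falls of 6. The miR-29 family, known to repress collagens, had 2 rises and 0 falls of 3, miR-29b rising by 1.01 ± 0.11, and miR-34 had 2 and 0 of 3.

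The remaining lists on day 4 were smooth muscle and fibroblast with 2 rises and 3 falls of 5 (miR-214 0.50 ± 0.10, miR-143 -0.59 ± 0.10), epithelium with 0 and 1 of 5, miR-181 with 0 and 2 of 4, and Dlk1-Dio3 with 3 and 13 of 30, against 13 and 5 with the 75th percentile over all miRNAs. With that percentile, smooth muscle and fibroblast had 2 and 1, and epithelium 2 and 0. Smooth muscle and fibroblast had 3 and 1 with quantile normalisation and in the deposited table, and 1 and 3 without scaling. The miR-23/24/27 list had 0 rises and 4 falls of 5, although its mean was positive under quantile normalisation and in the deposited table, at 0.11 and 0.07. miR-221 with miR-222 had 2 rises of 2, liver and pancreas 2 falls of 2, endothelium 1 fall of 2, and erythrocyte and hypoxia 0 changes of 2 and 1. The endothelium fall was that of miR-126* (-0.25 ± 0.10), positive under 3 other scalings. The muscle list had 0 rises and 2 falls of 5, miR-1 and miR-499 (-1.03 ± 0.18); miR-133a and miR-133b changed by -1.62 ± 0.72 and -2.10 ± 0.89 and did not pass.

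**Figure D2:**
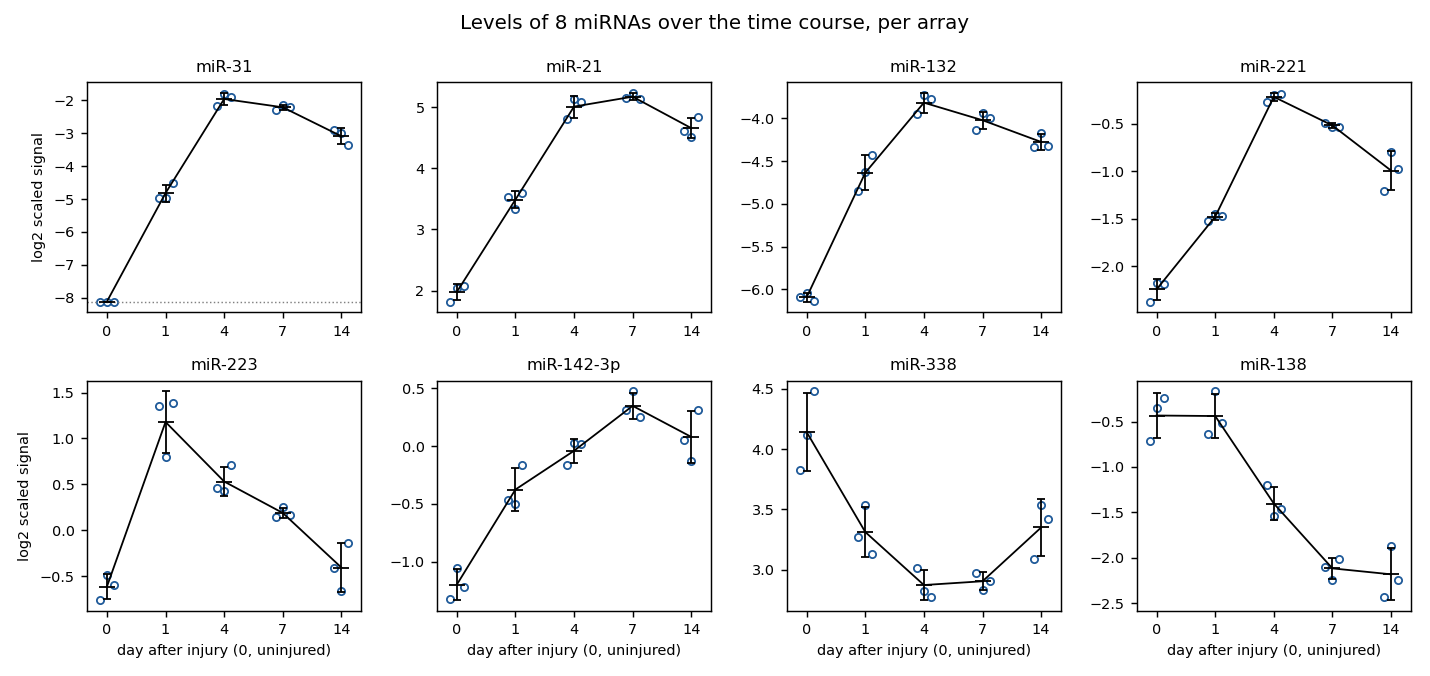
Log2 scaled signal (y axis) of 8 miRNAs by day after injury (x axis, day 0 uninjured); points are arrays, the line joins group means, bars are SD (n = 3), and the dotted line is the floor. miR-31 goes from the floor of -8.11 to -1.96 on day 4, and miR-338 from 4.14 to 2.87.

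On day 7 the same leading miRNAs stood out. miR-21 was 9.13-fold above uninjured nerve (log2 3.19 ± 0.12) and miR-31 at least 40.2-fold. miR-142-3p of blood-derived cells rose 2.92-fold, whereas the myeloid miR-223 was 1.74-fold higher. miR-138 fell by 1.69 ± 0.17 and miR-338 by 1.24 ± 0.16. miR-99a and miR-100, which are transcribed from let-7 and miR-125b clusters, fell by 1.42 ± 0.13 and 1.22 ± 0.14.

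The day 7 comparison called 145 of 231 miRNAs, 40 higher and 105 lower, with no overlap for 173 (74.9%; chance gives 10%) and a median change of -0.32. More rose than fell with the 75th percentile over all miRNAs (82 to 63), while the split was 59 to 74 with quantile normalisation, 42 to 87 without scaling and 55 to 61 in the deposited table. Held under 5 scalings were 37 rises and 48 falls, and without day 14 replicate 3 the split was 56 to 87.

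Other rises on day 7 were those of miR-18a (2.05 ± 0.16), miR-222 (1.87 ± 0.19), miR-221 (1.73 ± 0.10), miR-146b (1.68 ± 0.13), miR-34b (1.55 ± 0.15) and miR-142-5p (1.31 ± 0.14). miR-130b, miR-34c and miR-132 were at least 6.95-fold, 4.30-fold and 4.20-fold higher. Other falls were those of miR-33 (-1.69 ± 0.19), miR-32 (-1.40 ± 0.21), miR-499 (-1.37 ± 0.18), miR-125b* (-1.37 ± 0.24), miR-9* (-1.22 ± 0.13), miR-9 (-1.07 ± 0.15) and miR-210 (-0.75 ± 0.15), the last induced by hypoxia in many cells. miR-1 fell by 2.65 ± 0.96 (adjusted p = 0.0261), and without day 0 replicate 1 the change was -1.23, with adjusted p = 0.11; it also did not pass without day 7 replicate 1 (-2.00, adjusted p = 0.116). miR-29a rose by 0.28 ± 0.11. miR-34a (-0.29), miR-140 (0.07), miR-182 (-0.36), miR-206 (-0.22) and miR-451 (-0.33) did not pass.

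Lists on day 7 gave 0 rises and 8 falls for let-7 (mean -0.78, camera adjusted p = 0.022), led by let-7c (-1.01 ± 0.10), and 8 rises and 2 falls of 11 for miR-17-92 (mean 0.54, adjusted p = 0.00301). Both lost their call with an estimated correlation (adjusted p = 0.728). Let-7 had 4 falls with quantile normalisation (mean -0.23) and 3 in the deposited table (mean -0.21), and was not called there or without scaling. Myelinating glia again had 0 and 5 of 5 (mean -1.09, camera adjusted p = 0.0883, fry adjusted p = 0.000155), with 3 falls with quantile normalisation and in the deposited table. The miR-10/196 list had 0 and 5 of 5 (miR-196b -0.97 ± 0.11), and miR-30 had 0 and 5 of 5. Fry gave these 2 small adjusted p-values too (1.82e-05 and 0.000443), although camera did not call them. The neuron list had 2 rises and 3 falls of 8, with miR-7a (1.01 ± 0.10) and miR-218 (-0.98 ± 0.14); its mean was 0.05, its median -0.08 and its test pointed up. The leukocyte list had 3 and 1 of 5, miR-150 being lower (-0.73 ± 0.11), and the inflammation list 2 and 1 of 3 (miR-146a -0.42 ± 0.10). Smooth muscle and fibroblast had 2 rises, of miR-214 (0.73 ± 0.10) and miR-199a-5p (0.58 ± 0.11), both of a transcript active in mesenchymal cells, and 2 falls, of miR-145 (-0.60 ± 0.11) and miR-143 (-0.50 ± 0.10), known from contractile smooth muscle. miR-15/16 with miR-322 and miR-503 had 3 and 3 of 6, miR-29 had 2 and 0 of 3, miR-34 had 2 and 0 of 3, and miR-181 had 0 and 2 of 4. miR-23/24/27 had 0 and 3 of 5, its mean being positive under 3 of the other scalings, and Dlk1-Dio3 had 0 and 12 of 30, among them miR-434 (-0.60 ± 0.10). The Dlk1-Dio3 counts were 9 and 2 with the 75th percentile over all miRNAs, 2 and 4 with quantile normalisation and in the deposited table, and 0 and 6 without scaling. miR-221 with miR-222 had 2 rises of 2, liver and pancreas 2 falls of 2, endothelium 1 fall of 2, epithelium 1 fall of 5, muscle 2 falls of 5, hypoxia 1 fall of 1, and erythrocyte 0 changes of 2.

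On day 14 the leading rises were those of the earlier days, joined by miR-455. miR-31 was at least 21.9-fold and miR-21 6.40-fold (log2 2.68 ± 0.12) above uninjured nerve. miR-455, encoded within a fibrillar collagen gene, rose by 1.42 ± 0.10, after -0.37 on day 1. miR-138 stayed low, at -1.75 ± 0.17, and miR-338 was lower by 0.79 ± 0.16 on the log2 scale, a call not held under 5 scalings. miR-223 changed by 0.21 ± 0.16 and did not pass, whereas miR-142-3p rose by 1.28 ± 0.13.

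On day 14, 154 of 231 miRNAs passed, 37 higher and 117 lower, with no overlap for 145 (62.8%; chance gives 10%) and a median change of -0.37. The split reversed with the 75th percentile over all miRNAs (70 to 54) and without scaling (64 to 42), and was 61 to 83 with quantile normalisation and 54 to 69 in the deposited table; 35 rises and 35 falls held under 5 scalings. Without day 14 replicate 3, 45 rose and 92 fell.

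Other rises on day 14 were those of miR-146b (1.64 ± 0.13), miR-18a (1.37 ± 0.16), miR-222 (1.30 ± 0.19), miR-221 (1.25 ± 0.10), miR-34b (1.21 ± 0.15) and miR-142-5p (1.20 ± 0.14). miR-130b, miR-132 and miR-34c were at least 3.74-fold, 3.52-fold and 2.99-fold higher. The largest falls were those of miR-32 (-1.80 ± 0.21), miR-125b* (-1.60 ± 0.24), miR-551b (-1.56 ± 0.29, detected on 1 array in each group), miR-499 (-1.51 ± 0.18), miR-33 (-1.42 ± 0.19), miR-99a (-1.39 ± 0.13), miR-598-3p (-1.37 ± 0.15) and miR-99a* (-1.33 ± 0.21). miR-9 and miR-137 fell by 1.00 ± 0.15 and 0.98 ± 0.16, and miR-182, miR-210 and miR-34a by 0.88 ± 0.20, 0.67 ± 0.15 and 0.40 ± 0.13, the fall of miR-34a having the opposite sign under 2 other scalings. miR-92b passed the test with a lower value but was detected on 0 day 0 arrays and 1 day 14 array. miR-1 (-0.81), miR-29a (0.20), miR-140 (0.22), miR-206 (0.39) and miR-451 (-0.73) did not pass.

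In the day 14 lists, miR-17-92 had 8 rises and 0 falls of 11 (mean 0.54, camera adjusted p = 0.000249), including miR-19b (0.87 ± 0.10) and miR-106b (0.72 ± 0.11). Let-7 had 0 and 8 of 8 (mean -0.68, adjusted p = 0.028), and the inflammation list 2 and 0 of 3 (mean 1.41, adjusted p = 0.0264). With an estimated correlation each had adjusted p = 0.728. Under the other 4 scalings let-7 had 4 or 5 falls with means from -0.24 to -0.32, and it was called only with the 75th percentile over all miRNAs, as was the inflammation list. Myelinating glia had 0 and 4 of 5 (mean -0.99, camera adjusted p = 0.171), with 3 falls with the 75th percentile over all miRNAs and 2 under each of the other 3 scalings, miR-10/196 had 0 and 5 of 5, led by miR-196b (-1.08 ± 0.11), and miR-30 had 0 and 3 of 5. With the 75th percentile over all miRNAs and without scaling, miR-10/196 had 2 falls each (means -0.25 and -0.23), and miR-30 had 1 rise with 2 falls and 1 rise with 0 falls. The neuron list had 1 rise and 4 falls of 8, with miR-218 at -1.06 ± 0.14; its mean was -0.23 and was positive under the other 4 scalings. The leukocyte list had 3 and 1 of 5, with miR-342-3p up (0.36 ± 0.11) and miR-150 down (-0.69 ± 0.11). miR-15/16 with miR-322 and miR-503 had 3 and 1 of 6, miR-29 had 1 and 0 of 3, miR-34 had 2 and 1 of 3, and miR-181 had 1 and 0 of 4 (miR-181d 0.48 ± 0.13), with 4 rises with the 75th percentile over all miRNAs and without scaling and 2 with quantile normalisation and in the deposited table. Smooth muscle and fibroblast had 2 and 2 of 5, with miR-145 at -0.76 ± 0.11, and epithelium 0 and 3 of 5, with miR-183 at -0.73 ± 0.14. Epithelium had 2 and 2 with the 75th percentile over all miRNAs and without scaling, 2 and 3 with quantile normalisation, and 1 and 3 in the deposited table. miR-23/24/27 had 0 and 1 of 5 with a mean of -0.15 that was positive under the other 4 scalings, and Dlk1-Dio3 had 0 and 20 of 30, among them miR-376b-5p (-1.005 ± 0.162). The Dlk1-Dio3 counts were 2 and 4 with the 75th percentile over all miRNAs, 2 and 2 without scaling, 2 and 12 with quantile normalisation and 1 and 12 in the deposited table. miR-221 with miR-222 had 2 rises of 2, and endothelium and liver and pancreas 2 falls of 2 each. Muscle had 1 fall of 5 (miR-499), hypoxia 1 fall of 1, and erythrocyte 1 fall of 2, miR-144 (-1.54 ± 0.58, adjusted p = 0.0305). miR-144 did not pass under any of the other 4 scalings or without day 0 replicate 1 (-1.15, adjusted p = 0.12).

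Adjusted over the list alone, the counts were those given for all lists and times except 3. Endothelium had 2 falls in place of 1 on day 4, epithelium 1 rise in place of 2 on day 1, and miR-34 gained 1 fall on day 7. List means changed sign under at least 1 of the other 4 scalings for miR-23/24/27 at all 4 times, miR-30 and miR-29 on day 1, miR-181 on days 1 and 7, endothelium and Dlk1-Dio3 on days 4 and 7, smooth muscle and fibroblast on days 4 and 14, epithelium on days 4 and 7, neuron on day 14, and miR-15/16, erythrocyte and hypoxia on day 4. Of the 88 pairs of list and time, 63 had a number of rises or of falls that moved by more than 1.5 times under at least 1 other scaling, and in 16 the balance of rises and falls turned. The sign of a list's mean differed from its median or its camera direction in a few tests that did not pass, among them smooth muscle and fibroblast on day 4 (mean -0.11, direction up) and Dlk1-Dio3 on day 4 (mean -0.15, direction up).

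**Figure D3:**
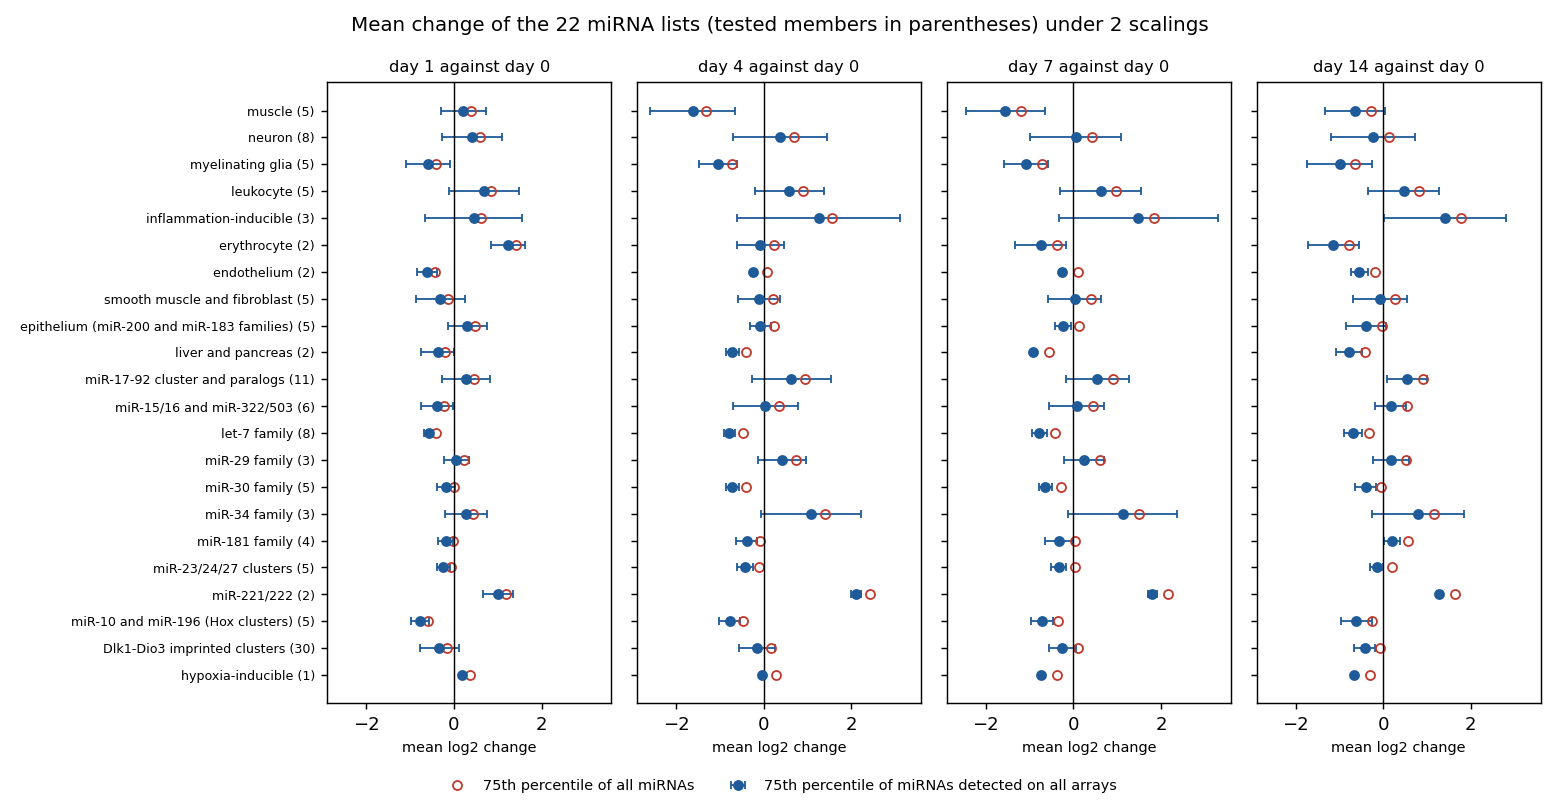
Mean log2 change (x axis) of the tested members of each of the 22 lists (y axis) at 4 times against day 0; filled circles with bars are means ± SD over members under the main scaling, and open circles are means with the 75th percentile over all miRNAs. The let-7 mean lies between -0.58 and -0.78 and stays below 0 under both scalings.

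**Figure D4:**
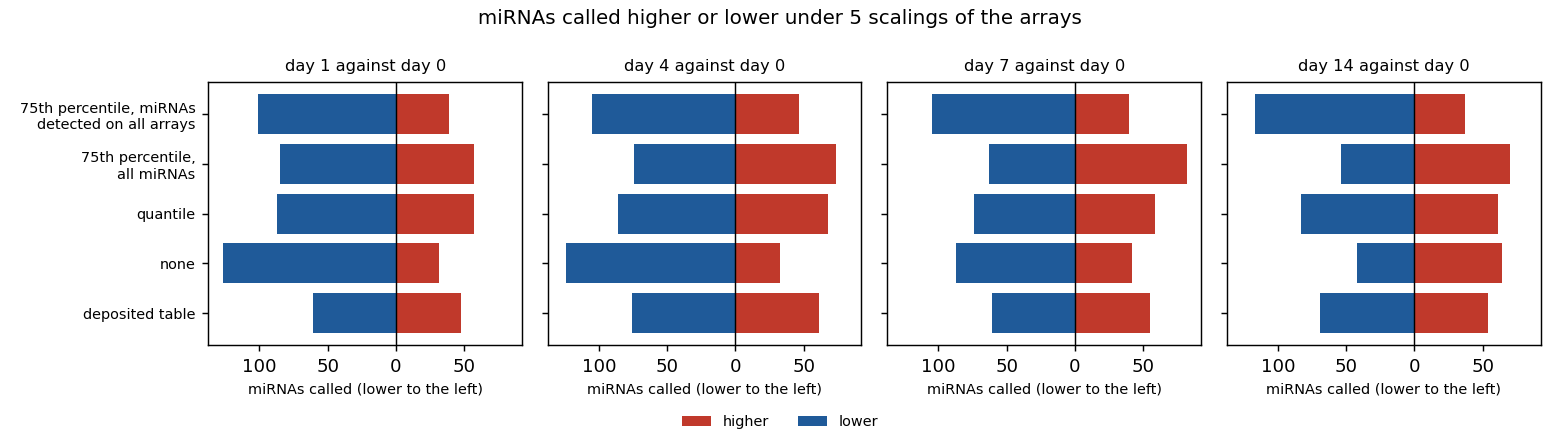
Number of miRNAs called lower (left) and higher (right) than day 0 (x axis) under 5 scalings (y axis) at each time. Rises number 39, 47, 40 and 37 with the main scaling and 57, 74, 82 and 70 with the 75th percentile over all miRNAs.

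Comparing consecutive times asks when the injured nerve changed most. Day 1 and day 4 were scanned on different dates, whereas day 4, day 7 and day 14 replicates 1 and 2 shared a scan date. A larger count from day 1 to day 4 than later can therefore not be told apart from an effect of the scan date. From day 1 to day 4 miR-31 rose by 2.86 ± 0.14, miR-21 by 1.52 ± 0.12, and the X-linked neighbours miR-542-3p and miR-503 by 1.42 ± 0.14 and 1.40 ± 0.13. miR-351, not detected on day 1, was at least 2.13-fold higher. Muscle miR-1, miR-133b and miR-133a fell by 2.94 ± 0.96, 2.59 ± 0.89 and 2.05 ± 0.72, miR-327 fell by 1.92 ± 0.49, and miR-760-3p, not detected on day 4, was at least 3.56-fold lower. In total 119 miRNAs passed, 64 higher and 55 lower, and 45 rises and 39 falls held under 5 scalings. The groups did not overlap for 140 (60.61%, chance gives 10%). The split turned to 36 higher and 124 lower with control features and 29 and 50 with normexp. It also turned without day 14 replicate 3 (59 and 75), without day 1 replicate 1 (48 and 62) and without day 0 replicate 2 (58 and 59). The 3 muscle falls each lost the call without day 1 replicate 1, without day 1 replicate 3, and without day 4 replicate 2 or 3, with miR-1 ranging from -2.66 to -2.85 there.

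From day 4 to day 7, 14 miRNAs passed, 3 higher and 11 lower, of which 2 and 5 held under 5 scalings. The groups did not overlap for 117 miRNAs (50.65%, chance gives 10%). The median SD was 0.079 on day 4 and 0.063 on day 7, but 0.161 to 0.185 in the other groups. The test uses the spread of all groups, so a low count does not show that both days were alike. The split depended on the scaling: it was 24 to 7 without scaling, 18 to 16 with quantile normalisation, 11 to 11 with the 75th percentile over all miRNAs, 8 to 14 in the deposited table and 94 to 9 with control features. The rises were those of miR-30c-1* (1.26 ± 0.29, adjusted p = 0.0178), miR-455 (0.56 ± 0.10, adjusted p = 0.00501) and miR-335 (0.51 ± 0.13, adjusted p = 0.0295). miR-21* fell by 1.02 ± 0.15 and miR-466b by 0.92 ± 0.21. miR-878, miR-672 and miR-743a, detected on all day 4 arrays and no day 7 array, were at least 2.37-fold, 2.29-fold and 1.99-fold lower. The count ranged from 5 to 18 when single arrays were left out, being 5 without day 4 replicate 1, without day 4 replicate 3 or without day 7 replicate 1, and 7 and 9 without day 7 replicates 2 and 3.

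From day 7 to day 14, 32 miRNAs passed, 11 higher and 21 lower, of which 7 and 3 held under 5 scalings. The groups did not overlap for 88 (38.1%, chance gives 10%). The excess of falls turned to 72 higher and 10 lower without scaling, 33 and 29 with the 75th percentile over all miRNAs and 32 and 26 with control features, and was 20 to 21 with quantile normalisation and 10 to 11 in the deposited table. Of the 4 tested members of the miR-181 family, known from lymphocyte development, 3 passed: miR-181c rose by 0.84 ± 0.16, miR-181d by 0.55 ± 0.13 and miR-181a by 0.52 ± 0.13, while miR-181b (0.26, adjusted p = 0.157) did not pass, and the family was not tested as a set here. miR-455 rose by 0.49 ± 0.10, and miR-674-5p by 0.71 ± 0.21, the latter with the opposite sign under 3 alternatives. miR-30c-1*, miR-327, miR-551b, miR-21* and miR-137 fell by 1.68 ± 0.29, 1.65 ± 0.49, 1.19 ± 0.29, 0.99 ± 0.15 and 0.93 ± 0.16. Within the slide that held 3 day 7 and 2 day 14 arrays, 14 miRNAs passed, among them miR-181c (0.87 ± 0.17), miR-455 (0.54 ± 0.10) and falls of miR-31 (-0.74 ± 0.10) and miR-223 (-0.72 ± 0.11); miR-181a and miR-181d did not pass there (adjusted p = 0.0797 and 0.0786). Rises and falls numbered 4 and 24 without day 14 replicate 3, 6 and 27 without day 14 replicate 2, and 25 and 20, the balance turned, without day 14 replicate 1. They were 4 and 10, 3 and 8, and 5 and 15 without day 7 replicates 1, 2 and 3, and 19 and 26 without day 0 replicate 1.

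Over the whole time course, 199 of 231 miRNAs differed between the 5 groups by the F test, most of which also lie on different slides. The 10 with the smallest p were miR-31 (F = 612, adjusted p = 1.54e-12), miR-21 (F = 253, adjusted p = 2.57e-10), miR-132, miR-221, miR-455, miR-130b, miR-18a, miR-21*, miR-34c and miR-146b. Of these, miR-31, miR-132, miR-130b, miR-21* and miR-34c were not detected on day 0. For miR-31 the day 0 values were all set to the floor, without spread, so its F depends on the floor. At all 4 times, 17 miRNAs were higher than in uninjured nerve and 59 were lower. Of the 17, 9 held under 5 scalings at every time: miR-21, miR-31, miR-132, miR-142-3p, miR-142-5p, miR-146b, miR-18a, miR-221 and miR-222. Among the 59, the 12 that held were miR-10b, miR-148b-3p, miR-152, miR-196b, miR-22*, miR-26b, miR-32, miR-33, miR-340-3p, miR-352, miR-98 and miR-99a; these names were taken after their values were seen. The 4 comparisons share the 3 day 0 arrays, which could not be split further. In 100 simulations of unchanged groups against shared controls, 0 miRNAs were called at all 4 times. Unchanged groups give hardly any calls, so this outcome was nearly fixed and does not show how much the shared arrays add. Independent lists of these sizes would share 0.22 rises and 10.6 falls, a figure that leaves out the shared arrays.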

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

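The tests of the scaling, the slide, muscle RNA, the makeup of leukocytes and blood were chosen only after the result was seen; the counts over other groupings of the arrays were planned before.

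Some miRNAs went one way at one time and the opposite way at another, each past the test at both times. They were picked for these opposite calls and for a difference between the times past the limma test, with the largest such difference given for each, so that this test restates the choice. Between day 1 and day 14 the change from day 0 differed by -1.78 for miR-137 (0.80 on day 1, -0.98 on day 14), by -1.36 for miR-145 (0.59 to -0.76), by -1.88 for miR-182 (1.00 to -0.88), by -0.92 for miR-96 and by -2.16 for miR-30c-1*. The opposite turn, from lower on day 1 to higher on day 14, was 1.05 for miR-335, 1.79 for miR-455, 0.64 for miR-532-5p and 1.02 for miR-542-5p. From lower on day 1 to higher on day 7 the difference was 1.16 for miR-199a-5p, 1.32 for miR-214, 1.22 for miR-322 and 1.64 for miR-542-3p, and from day 1 to day 4 it was 0.76 for miR-374, 1.04 for miR-541 and 0.85 for miR-674-3p. For miR-324-3p the difference from day 4 to day 14 was -0.72. The signs at both times were also opposite under the other 4 scalings for all of these except miR-532-5p (3 of 4) and miR-324-3p (0 of 4). These miRNAs were picked by a rule from all tested, not by the rule for named miRNAs.

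Signals outside the main measurement also differed from day 0. The bright control features hur_1, hur_2, hur_4, hur_6 and mr_1 were higher on day 14 than on day 0 by 0.55, 0.94, 0.66, 0.69 and 0.90 on the log2 scale of unscaled signal. The bright corner control feature went the other way, by -4.45 on day 1, -1.13 on day 4, -0.23 on day 7 and -0.80 on day 14. All day 1 arrays lay on 1 slide, so its low value there may belong to the slide, and its bearing on the day 1 calls was not tested. miR-184, not tested because it was detected on 1 array alone (day 14 replicate 2), lay 4.76 on the log2 scale above the floor, to which its values on all day 0 arrays were set because they lay below it, so that no exact difference is known.

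More miRNAs fell than rose at each time against day 0 under the main scaling. On days 4, 7 and 14 the highest shares of rises among the calls under 5 scalings were 50%, 56.55% and 60.38%, and the scaling may account for the excess of falls there. On day 1 the highest share was 44.04%, with a 95% binomial interval reaching 53.9%. That interval treats the called miRNAs as independent, which they are not, so it does not measure the uncertainty of the share. The median change went from -0.26 to between -0.39 and -0.05 under the other 4 scalings, so the scaling stays open there too. The slide remains open at all 4 times, since day 0 fills a slide of its own: 0 slides held day 0 or day 1 arrays together with another group, and slide and time after injury cannot be told apart. A wider loss of miRNAs after injury is an untested biological reading that also stays open.

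The muscle miRNAs differed between arrays of the same group, most on day 0. The list's mean spanned 3.62 on the log2 scale within the slide of day 0 and the slide means spanned 1.83, but day 0 fills that slide, so this restates the pattern and settles nothing about slides. Muscle RNA carried in with some segments may be the source. The median correlation between members' deviations from their group means was 0.854, above 99.45% of random sets, and miR-1 was highest, at 3.12 on the log2 scale, on day 0 replicate 1. But miR-1 with miR-133a, and miR-133b with miR-206, are neighbouring genes that changed together. Being neighbours does not cover the other pairs among them. miR-133b had correlations of 0.9863 with miR-1 and 0.9654 with miR-133a, and miR-206 had 0.8307 and 0.878 with the same miRNAs. Muscle RNA carried in and a difference in the nerve itself could both move these members together, so the correlation does not tell these sources apart. miR-499 stood apart, with correlations from -0.41 to -0.18 with the other members, so its fall at all 4 times is not covered by muscle RNA carried in. That fall at all 4 times did not hold under 5 scalings: on day 1 it did not pass with the 75th percentile over all miRNAs or in the deposited table. A difference between animals in the nerve itself stays open and untested.

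miR-223 was highest on day 1, whereas miR-142-3p and miR-142-5p were highest on day 7. From day 1 to day 7 the mean of both miR-142 arms changed by 1.51 ± 0.13 more than miR-223 on the log2 scale. In it, miR-223 fell by 0.99 ± 0.16 and miR-142-3p rose by 0.72 ± 0.13, while miR-142-5p (0.31 ± 0.14, limma adjusted p = 0.0659) did not pass. The days compared were those of the pattern, so the size of the difference restates it. Leukocytes of fixed makeup would move these miRNAs the same way, so the opposite changes of miR-223 and miR-142-3p argue against a single rise of them. This covers those miRNAs only, and day 1 and day 7 lay on different slides, so an effect of the slide is not excluded. A change in the mix of blood-derived cells, or of miRNA levels within cells, stays open and was not tested. Blood left in the segments stays open for part of miR-223 on day 1, because blood with the lowest ratio of miR-223 to miR-451 seen on a day 0 array could give from 17.9% to 61.9% of it, by array. The erythroid miR-451 fell by 1.83 ± 0.575 from day 1 to day 7.

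Other groupings of the same arrays were counted for each result. For each comparison of 3 arrays against 3 only 10 groupings exist, too few for a share under 0.05, and only 1 of the 10, the real one, gave as many calls: the real counts were 140, 152, 145 and 154 against day 0 and 119, 14 and 32 for consecutive times, and the highest of the other groupings was 0 in each. For the F test, 1 of 100 groupings of the 15 arrays, the real one, gave 199, the highest other gave 48, and chance can be excluded. Slide and scan date are not excluded by this, because the real groups nearly follow the slides and the other groupings mix them. For the 76 miRNAs called the same way at all 4 times, the real grouping was 1 of 100 and the others all gave 0, so that they set no scale for this count and leave chance undecided. For the 12 list calls, 7 of 100 groupings gave as many, the highest other gave 18, and chance cannot be excluded.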

How the results depend on the processing

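The normexp, control-feature and left-out-pair alternatives, and the one without muscle and erythrocyte lists, were chosen after seeing the data; the other alternatives were planned. The counts against day 0 stayed within 1.5 times of the main ones under every alternative run except the 2-fold minimum, which by construction left 25, 36, 37 and 38 on days 1, 4, 7 and 14, with 25, 4 and 3 for consecutive times and 70 for the F test. Leaving out 1 array gave 116 to 150, 138 to 158, 133 to 150 and 137 to 165 calls against day 0, 90 to 134, 5 to 18 and 11 to 45 for consecutive times, 194 to 206 for the F test, 57 to 80 shared over 4 times and 9 to 13 list calls; where 2 arrays were left in a group, they were assumed to vary like the other groups. Signal over background limits miRNAs near the floor, such as miR-92b and miR-551b. The planned normexp on mean signals was not run.

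With a replicate block the counts were 147, 156, 151 and 156 against day 0, 127, 13 and 42 for consecutive times, 207 by F test, 80 shared and 12 list calls. Deviations from group means had a correlation over 0.1 in 8 of 30 pairs with the same number (-0.782 to 0.594), and in 0 of 10 pairs of groups did all 3 exceed 0.1, so the numbers were not taken as pairs.

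Day 7 against day 4 moved from 14 to 22 with the 75th percentile over all miRNAs, 34 with quantile normalisation, 31 without scaling, 22 in the deposited table, 103 with control features and 74 with only the 2 groups' arrays, and to 5 with miRNAs detected on all arrays, where fewer are tested. Day 14 against day 7 moved from 32 to 62, 82 and 21 with the all-miRNA percentile, no scaling and the deposited table, to 58 with control features, 19 with the brightest probe, 18 with miRNAs detected on all arrays and 14 on the shared slide, which has fewer arrays. Day 4 against day 1 was 79 with normexp. Shared calls were 42 without scaling, 45 in the deposited table and 147 with control features. List calls were 5 with quantile normalisation, 3 without scaling and 0 with an estimated correlation in camera. Unless stated, the cause was not tested.

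These log2 changes reversed, counting only those that passed in the main analysis or under the alternative, and the cause was not tested. With quantile normalisation: day 1 miR-27b 0.012, miR-24 0.21; day 4 miR-34a 0.30, miR-140 0.23, miR-126* 0.043, miR-199a-3p 0.305, miR-23a 0.051, miR-27b 0.15, miR-24 0.18. On day 7 they were miR-34a 0.28, miR-126* 0.022, miR-126 0.29, miR-23a 0.15, miR-27b 0.22 and miR-24 0.20, and on day 14 miR-34a 0.033, miR-126 0.048, miR-195 0.16, miR-23a 0.051, miR-24 0.19 and miR-27b 0.40. In the deposited table they were miR-140 0.19, miR-27b 0.0078 and miR-24 0.20 on day 1, and miR-34a 0.26, miR-140 0.25, miR-126* 0.085, miR-199a-3p 0.22, miR-23a 0.040, miR-27b 0.13 and miR-24 0.15 on day 4. There, day 7 gave miR-34a 0.24, miR-126* 0.044, miR-23a 0.12, miR-27b 0.18 and miR-24 0.17, and day 14 miR-92b 0.24, miR-34a 0.031, miR-126 0.071, miR-195 0.14, miR-23a 0.040, miR-24 0.17 and miR-27b 0.28. With the 75th percentile over all miRNAs, day 4 gave miR-140 0.056, miR-126* 0.067, miR-29c 0.23 and miR-24 0.022, and day 7 miR-126* 0.068, miR-181b 0.25, miR-181d 0.30 and miR-27b 0.0074. Its day 14 values were miR-146a 0.28, miR-195 0.061, miR-24 0.28, miR-27b 0.28 and miR-196c 0.0057. Without scaling on day 14, miR-195 was 0.086, miR-23a 0.0057, miR-24 0.31 and miR-196c 0.030. With control features, day 1 gave miR-29a -0.32, miR-20a -0.021, miR-29b -0.086 and miR-30d -0.27, day 4 miR-29a -0.38, miR-182 -0.40, miR-214 -0.20 and miR-15b -0.018, day 7 miR-29a -0.13 and miR-140 -0.34, and day 14 miR-342-3p -0.010, miR-322 -0.098, miR-181b -0.21, miR-181a -0.25 and miR-181c -0.29. Leaving out both day 0 replicate 1 and day 14 replicate 3 gave miR-1 1.66 on day 1 (adjusted p = 0.0427). For miR-674-5p, day 14 against day 7 was -0.13 with the brightest probe, -0.053 in the deposited table and -0.0030 with normexp.

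Of 372 named values, direction and call both held for 315 with the 75th percentile over all miRNAs, 309 with quantile normalisation, 322 without scaling, 303 with control features, 340 with the brightest probe, 343 with the scanner software's total gene signal and 337 with normexp, and for 280 of 371 in the deposited table. No list test that was called, in the main analysis or under an alternative, changed its camera direction. Means of lists that were not called did change sign with the scaling, such as miR-23/24/27 on day 14 (-0.15 in the main analysis, 0.11 to 0.23 under the other 4 scalings). These counts leave out size, which was less stable. The day 1 change of miR-31 on the log2 scale was 3.29 in the main analysis, 2.62 with total gene signal and 0.46 with normexp. miR-31 was not detected on day 0, so these values depend on the floor or offset and are not measured rises. The added offset of normexp shrinks changes of weak signals. Against day 0, control features gave 24 rises and 165 falls on day 1, 24 and 182 on day 4, 24 and 169 on day 7, and 21 and 168 on day 14, and normexp gave 40 and 67, 38 and 85, 34 and 123, and 24 and 131. The control features themselves mostly rose after injury, and what they target is not stated. Scaling by them therefore lowers the miRNA values after injury. Leaving out both doubted arrays gave 118, 145, 133 and 137 calls against day 0, and leaving out the muscle and erythrocyte lists gave 138, 151, 144 and 153.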

Other observations

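The tests of neighbouring genes and of hairpin arms were planned before their results were seen; the clusters and hairpins named here were chosen after.

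miRNAs whose genes lie close together tended to change together. Among the 25 clusters of tested miRNAs within 10 kb, the pairs miR-221 with miR-222 and miR-34b with miR-34c both had correlations of 0.974 over the 5 group means. The cluster of miR-182, miR-183 and miR-96 had a mean correlation of 0.957, going from a mean log2 change of 0.54 on day 1 to -0.70 on day 14. The cluster of miR-322, miR-351, miR-450a, miR-503 and miR-542-3p, on the X chromosome, went from -0.73 on day 1 to 0.53 on day 4 and 0.41 on day 14, with a mean correlation of 0.795. miR-106b, miR-25 and miR-93 had a mean log2 change of 0.59 on day 14. Not all neighbours moved together: miR-15b and miR-16 had a correlation of -0.63, and the 22 tested members of the larger Dlk1-Dio3 cluster a mean of 0.29.

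Shared transcription of neighbouring genes may explain this, as a hypothesis. The mean correlation between neighbours, averaged over clusters, was 0.58, against a mean of 0.0913 in 10000 random pairings of which 95% were below 0.254 (p = 1e-04, the smallest that these can give). The 2 arms of one hairpin may likewise follow their shared precursor: the mean correlation between arms was 0.459 over 34 hairpins, 28 of them above 0, against 0.138 at random with 95% below 0.284 (p = 1e-04, again the smallest possible). Arms of miR-9 and miR-99a had correlations of 0.993 and 0.987, whereas those of miR-125a, miR-340, miR-99b and miR-1 had -0.76, -0.75, -0.73 and -0.69. Neighbouring genes and arms of similar sequence could share probe signal, which was not tested.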
